A study of Coccomyxa subellipsoidea C-169 with 6 samples.

How the data were processed

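The data are RNA-seq libraries of Coccomyxa subellipsoidea C-169 cultures in stationary phase, 3 from wild type and 3 labelled CsubMADS1 OX. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a directional kit. The submitters' processing notes name FastQC, Trim Galore, HISAT and HTSeq, without versions. The genome build and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. The deposited files hold raw counts per gene, not normalized, for genes with at least 1 count in any of the 6 libraries. All 9490 locus tags matched the RefSeq annotation of assembly GCF_000258705.1 with 9915 genes, from which no coordinates are printed. Groups and replicate numbers were taken from the labels.

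Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (8575 genes), scaled by TMM, and tested with the robust quasi-likelihood F test for group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM, given as mean and SD over 3 libraries, and SE is the log2 fold change over the square root of F. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1 and was not used. The common dispersion gave a biological coefficient of variation of 19.8%. Library totals ran from 3771499 to 5336375 counts. Counting intervals are 95% exact (Clopper-Pearson), and they and the floor of 3 counts cover counting error only. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom between a pair being 7.09.

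The tests, the alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined. Lists were defined by patterns on product names. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, for the 23 lists with at least 5 tested members, with adjustment over lists. None of the 7 called lists held with an estimated correlation. Named genes were the MADS-box gene and the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM in the higher group, no overlap between groups and an informative product name. They were also the 2 largest in each direction without the name condition, and up to 4 members of each called list in its direction and 2 of each other list, by lowest p. The text names part of these. Genes with cilium product names were chosen after their values were seen.

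Alternatives were other scaling factors (DESeq2 median-ratio, library size only, upper quartile), other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, a stricter threshold, glmTreat, and for lists an estimated correlation, fry and a prior count of 0.5. Chosen after seeing the data were the fits without shifted runs, without stray list members, the member counts without OX replicate 3, and the runs. Strays were genes that a name pattern let in but that were judged not to belong, 2 to 13 in each called list. Member counts and medians include them. Runs came from binary segmentation of log2 fold changes, limited to 2 in size, with at least 10 genes on each side, 1000 permutations and a p of 0.001 per change point. A run had at least 20 genes and a median of at least 0.3 in size. A whole scaffold without a change point could be a run by these limits alone.

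The scripts were tested on simulated data for this comparison. Among 8554 tested genes, edgeR recovered 55 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and 3.16% of its calls were false. A list shifted 1.5-fold was called by camera with both correlations and by fry, with 0 other lists. Genes were simulated independently of each other, so this does not test list calls under correlation between genes. Far fewer genes were changed than were called in the data, and no library was given a shift of its own. The recovered and false shares therefore need not carry over to the data. A doubled stretch of 100 neighbours among 8543 genes was found as 1 run with all 100 genes.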

Results

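Messenger RNA was profiled in cultures of Coccomyxa subellipsoidea C-169, a unicellular green alga isolated in Antarctica. Cells were in stationary phase and were collected 3 hours before the dark period. The 6 libraries fell into 2 groups, with 3 from wild type (WT) and 3 labelled as overexpressing CsubMADS1 (labelled OX). Each group held 3 biological replicates per the labels' protocol. The sample titles do not tell how many lines the OX-labelled cultures come from. The p-values thus measure spread between cultures, and a change particular to 1 line cannot be told from an effect of the labelled gene. The files listed 9490 genes as raw counts. Total counts per library were 4953851, 4659434 and 3771499 in WT replicates 1 to 3 and 5336375, 4721278 and 3862791 in OX-labelled replicates 1 to 3. A count of 3, taken as the floor, stood for 0.588 to 0.759 CPM (counts scaled to the library total) across the libraries.

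The comparison of both groups addresses how transcript levels differ between cultures labelled as overexpressing a MADS-box gene and wild type. The targeted gene was looked at first. COCSUDRAFT_67545 was the 1 gene of the files with a MADS-box product name, MADS-box proteins being DNA-binding transcription factors, and its identity with CsubMADS1 rests on that name alone. Its level was 86.8 ± 7.72 CPM (SD, n = 3) in WT and 60.7 ± 7.0 CPM (SD, n = 3) in the OX-labelled libraries. The 3 WT libraries held 95.3, 80.2 and 85.0 CPM, and the 3 OX-labelled libraries held 68.5, 59.0 and 54.8 CPM. The log2 fold change was -0.51 (SE 0.18), which missed the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0535). The WT level was 1.43 times that of the OX-labelled libraries, with a 95% interval of 1.09 to 1.87. That interval and the unadjusted p of 0.0134 in the same edgeR test do not allow for the number of genes tested. The direction goes against the label, so the second group is called OX-labelled throughout, and every direction given here is that of the labels. With library size only as scaling the gene passed (edgeR adjusted p = 0.0295). Over all 14 other settings its adjusted p ranged from 0.0295 to 0.168, with the same sign in each, and 6 settings passed.

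**Figure D1:**
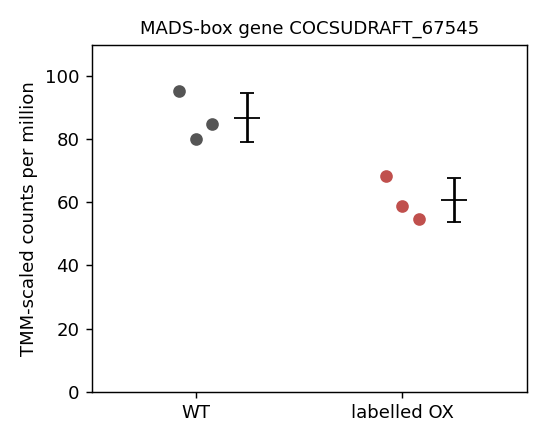
TMM-scaled CPM of the MADS-box gene COCSUDRAFT_67545 on the y axis, with 1 point per library for WT and for the libraries labelled OX, and a bar with whiskers for the mean and SD of 3 libraries. The 3 OX-labelled libraries lie between 54.8 and 68.5, all below the WT libraries, which lie between 80.2 and 95.3.

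Among 8575 genes tested, 1337 were higher and 770 lower in the OX-labelled libraries (edgeR, Benjamini-Hochberg adjusted p under 0.05). Of these, 760 higher and 172 lower genes had a fitted change of at least 2-fold. A test against a 2-fold change (edgeR glmTreat) called 174 higher and 8 lower genes. At an adjusted p under 0.01 in edgeR, 760 genes were higher and 206 lower. Of the changed genes, 863 had no informative product name. With library size only as scaling the split was 1140 higher and 995 lower, so that the share of higher calls was 53.4% in place of 63.5%. The groups did not overlap for 3676 genes (42.9%), where chance gives 10%. Leaving out 1 library moved these counts. Without WT replicates 1, 2 and 3 in turn, 1050, 1289 and 1250 genes were called, of which 737, 875 and 865 were higher and 313, 414 and 385 lower. Lower calls numbered 414 without OX replicate 1 and 1232 without OX replicate 3, and the lower genes changed at least 2-fold numbered 280 without OX replicate 2. OX replicate 3 stood apart from the other OX-labelled libraries on the second principal component (19.6% of variance), so counts without it, added after the data were seen, are given beside each called gene group. Of the 2107 calls, 902 (42.8%) were made in all 6 fits that leave out 1 library. Each of those fits had 1 library fewer to test with, so a lost call does not show that it rests on 1 library. Of the genes called without WT replicates 1, 2 and 3, 1040, 1276 and 1214 were among the 2107, with no change of sign.

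Several of the genes with the largest rises had few counts in WT. The BTB domain gene COCSUDRAFT_60007, whose domain is known for protein-protein contacts, had 0 counts in the WT libraries and 10.3 ± 1.75 CPM (SD, n = 3) in the OX-labelled libraries. It was at least 46.1-fold higher, taking 3 counts over the WT group as the floor, and at least 29.4-fold and 30.1-fold without WT replicates 1 and 2, where the floor rests on fewer counts in all. A 3-phosphoshikimate 1-carboxyvinyltransferase of the shikimate pathway, COCSUDRAFT_43409, had 2 counts over WT and 173 over the OX-labelled libraries, a ratio of 87.4 with a 95% exact counting interval of 23.8 to 727. Its OX-labelled libraries held 7.06, 9.19 and 24.1 CPM, and the ratio was 55.1 (14.7 to 463) without OX replicate 3 and 57.0 (15.6 to 475) without WT replicate 2. The uncharacterized gene COCSUDRAFT_62699 went from 3 counts to 1023, a ratio of 344 (118 to 1673). All 3 WT counts came from WT replicate 1, without which the gene was at least 219-fold higher, and the ratio was 225 (76.7 to 1092) without WT replicate 2. Its OX-labelled libraries held 40.2, 63.2 and 135 CPM, with a ratio of 232 (79.0 to 1130) without OX replicate 3. Fatty acid elongase COCSUDRAFT_48328, a 3-ketoacyl-CoA synthase that extends very long fatty acids, rose from 2.32 ± 0.370 to 108 ± 17.9 CPM (SD, n = 3), with a log2 fold change of 5.52 (SE 0.26, edgeR adjusted p = 5.2e-07). A second enzyme of that type, COCSUDRAFT_58870, rose by 3.93 on the log2 scale (SE 0.61), with 12, 29.1 and 7.29 CPM in the OX-labelled libraries and a log2 fold change of 3.20 without OX replicate 2. The sodium/sulfate symporter COCSUDRAFT_54015 rose by 4.35 on the log2 scale from 3.79 CPM, and the aldo/keto reductase COCSUDRAFT_34922 from 5.46 to 105 CPM.

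Falls were smaller. COCSUDRAFT_42518, with a SET7/9 N-terminal histone methyltransferase product name, fell from 27.2 ± 2.54 to 3.19 ± 1.31 CPM (SD, n = 3), a log2 fold change of -3.08 (SE 0.30, edgeR adjusted p = 6.67e-05). Another gene with this product name, COCSUDRAFT_55839, rose from 3.02 to 18.8 CPM. Elongation factor Tu, COCSUDRAFT_36392, which brings aminoacyl-tRNA to the ribosome, fell from 38.3 to 5.53 CPM. A transporter of the major facilitator superfamily, COCSUDRAFT_37582, fell from 29.1 to 6.44 CPM and the ATP-binding cassette transporter COCSUDRAFT_52664 from 243 to 79.1 CPM. PspA/IM30, COCSUDRAFT_10602, a membrane-associated protein of plastids and bacteria, fell from 494 to 143 CPM (edgeR adjusted p = 0.0411) and lies in a run of 236 neighbouring genes with a median log2 fold change of -0.36, of which 73 were called lower and 23 higher. Its OX-labelled libraries held 217, 185 and 27.9 CPM, and its adjusted p was 0.114 without WT replicate 1, 0.0899 without WT replicate 2, 0.0691 without WT replicate 3 and 0.0563 without OX replicate 2 in edgeR. Without OX replicate 3, which held its lowest level, the fold change was -1.30 with an edgeR adjusted p = 4.36e-05. The call was also lost without a filter on low counts (edgeR adjusted p = 0.0694), by the DESeq2 Wald test (adjusted p = 0.0791) and by limma-voom (adjusted p = 0.0606).

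Of 66 tested genes for photosystems, light harvesting and photosynthetic electron transport, 44 were higher, 0 lower and 22 did not pass, with 49 higher and 1 lower when adjusted over the list alone. The median log2 fold change was 1.08 (camera adjusted p = 4.37e-15 with a preset correlation). The call was lost with a camera adjusted p = 0.421 with an estimated correlation. The chlorophyll a-b binding proteins, the antenna proteins of the photosystems, were among the members with the lowest p. COCSUDRAFT_65904 rose from 727 ± 115 to 3465 ± 696 CPM and COCSUDRAFT_21950 from 737 ± 110 to 3064 ± 371 CPM (SD, n = 3). COCSUDRAFT_15915 rose by 2.50 on the log2 scale (SE 0.18, edgeR adjusted p = 5.78e-06). COCSUDRAFT_66689 had the largest fold of the family, from 50.1 to 1358 CPM, with a wide spread over the OX-labelled libraries (2222, 1370 and 481 CPM). These genes form a family of similar sequences, and how reads that match several members were counted is not given in the sources used here. Without OX replicate 3, 48 members were higher and 0 lower.

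Of 37 tested genes for chlorophyll, heme and carotenoid synthesis, 18 were higher, 2 lower and 17 did not pass, or 19 and 3 adjusted over the list alone (median 0.65, camera adjusted p = 0.000707, but adjusted p = 0.421 with an estimated correlation). Geranylgeranyl reductase COCSUDRAFT_31829, which makes the phytol tail of chlorophyll, rose from 178 to 462 CPM, and protochlorophyllide oxidoreductase COCSUDRAFT_65591 rose from 260 to 561 CPM. Of 22 genes for carbon fixation and carbon concentration, 6 were higher, 0 lower and 16 did not pass, or 7 and 0 adjusted over the list alone (median 0.33, camera adjusted p = 0.0105, but adjusted p = 0.421 with an estimated correlation). The Rubisco small chain COCSUDRAFT_65708 rose from 4475 ± 18.9 to 8403 ± 1299 CPM (SD, n = 3). Carbonic anhydrase COCSUDRAFT_54903 rose by 1.28 on the log2 scale, and lies in a run of 158 neighbouring genes with a median of 0.42, of which 54 were called higher and 2 lower. Without OX replicate 3 the counts of higher and lower members were 17 and 3 for pigments and 8 and 0 for carbon fixation. Of the listed genes, 8 for pigments and 2 for carbon fixation were judged strays and were not taken out of these counts.

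Of 51 tested genes for microtubules, actin and cytokinesis, 11 were higher, 2 lower and 38 did not pass, or 13 and 2 adjusted over the list alone (median 0.47, camera adjusted p = 0.000693, but adjusted p = 0.421 with an estimated correlation). Without OX replicate 3, 14 were higher and 3 lower. The outer dynein arm heavy chain COCSUDRAFT_14688, a motor protein of cilia in other organisms, rose from 1.40 ± 1.01 to 46.9 ± 15.9 CPM (SD, n = 3), with a log2 fold change of 5.10 (SE 0.42, edgeR adjusted p = 1.71e-05), or 5.75 without WT replicate 3, which held most of its WT counts. The gamma-tubulin gene COCSUDRAFT_14036 rose from 53.5 to 169 CPM and the alpha-tubulin gene COCSUDRAFT_31682 from 317 to 659 CPM. Both lie in runs of neighbouring genes with a median above 0, and of the members outside all runs 8 were higher and 2 lower. The kinesin COCSUDRAFT_45765, outside the runs, rose from 27.8 to 64.7 CPM.

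Of 194 ribosomal protein and translation factor genes, 50 were lower, 4 higher and 140 did not pass, or 56 and 4 adjusted over the list alone (median -0.34, camera adjusted p = 5.15e-07, but adjusted p = 0.421 with an estimated correlation). Ribosomal protein L27a, COCSUDRAFT_23296, fell from 3248 ± 425 to 1565 ± 108 CPM (SD, n = 3), and the asparagine-tRNA ligase COCSUDRAFT_15475 fell from 414 to 164 CPM. Of 126 genes for RNA splicing and RNA helicases, 22 were lower, 6 higher and 98 did not pass, or 21 and 6 adjusted over the list alone (median -0.29, camera adjusted p = 0.000256, but adjusted p = 0.421 with an estimated correlation). The LSM2 gene COCSUDRAFT_17813, part of the ring that binds U6 RNA, fell from 255 to 147 CPM, and a DEAD-domain gene, COCSUDRAFT_28415, fell from 99.0 to 42.2 CPM. The splicing list did not pass by fry (adjusted p = 0.0522). Without OX replicate 3, the lower members numbered 66 for ribosomes and translation, with 7 higher, and 37 for splicing, with 7 higher.

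Of 66 heat shock protein and chaperone genes, 14 were lower, 4 higher and 48 did not pass, or 15 and 4 adjusted over the list alone (median -0.20, camera adjusted p = 0.0105, but adjusted p = 0.50 with an estimated correlation). Heat shock protein 70, COCSUDRAFT_67628, fell from 789 ± 47.5 to 204 ± 156 CPM (SD, n = 3), with 137, 383 and 92.5 CPM in the OX-labelled libraries, and a log2 fold change of -1.95 that was -2.78 without OX replicate 2. Chaperonin 60B2, COCSUDRAFT_36901, which folds plastid proteins, fell from 1353 to 638 CPM and lies in a run of 95 neighbouring genes with a median of -0.44, of which 31 were called lower and 5 higher. A GroES-like protein, COCSUDRAFT_26878, fell from 1430 to 661 CPM, and this name is also given to the fold of alcohol dehydrogenases. Without OX replicate 3 the list was no longer called (camera adjusted p = 0.141), with 19 members lower and 8 higher. It was not called by fry either (adjusted p = 0.0744). Of its 71 listed genes, 13 were judged strays and were not taken out of these counts.

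**Figure D2:**
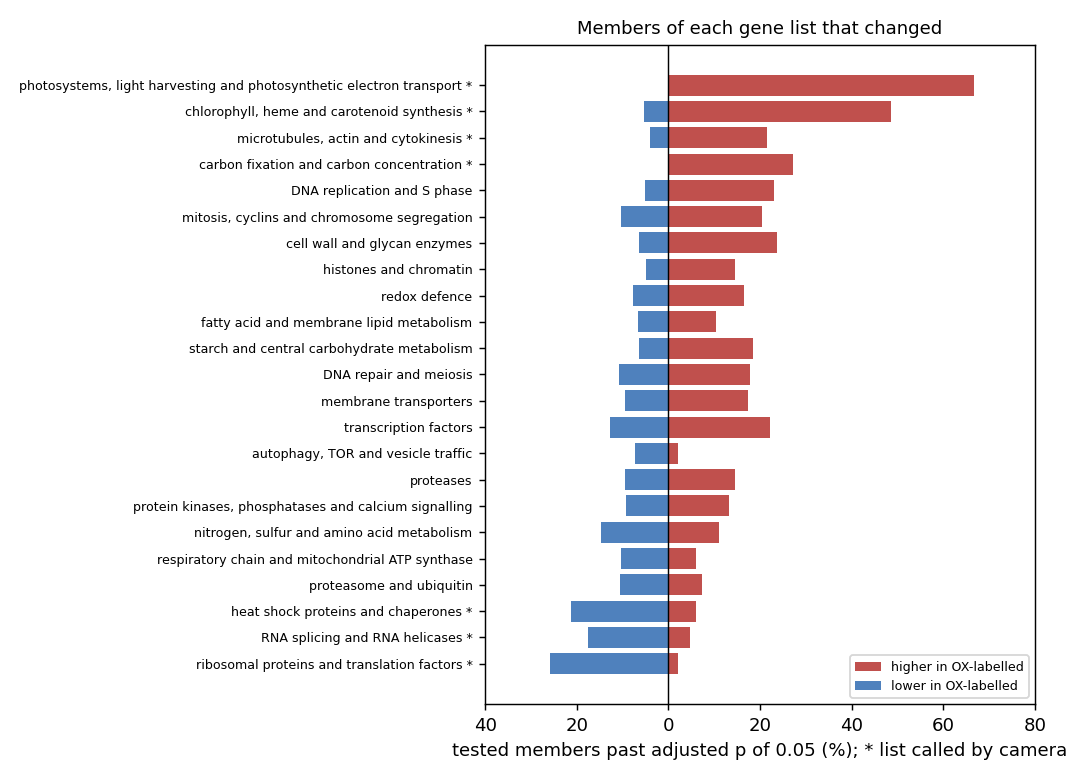
For each of 23 gene lists, the percent of its tested members that were higher (right) or lower (left) in the OX-labelled libraries at an edgeR adjusted p under 0.05, ordered by median log2 fold change, with an asterisk on the 7 lists called by camera with a preset correlation. The list of photosystems and light harvesting stands at the top with 44 of 66 members higher and 0 lower, and ribosomal proteins and translation factors at the bottom with 50 of 194 lower.

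The other 16 lists tested were not called, with camera adjusted p from 0.10 for proteasome and ubiquitin genes to 0.902 for membrane transporters. Of 39 DNA replication genes, 9 were higher and 2 lower, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.192), against 8 and 7 without OX replicate 3. This list passed without OX replicate 2 (camera adjusted p = 0.0466), and proteasome and ubiquitin genes passed as lower without OX replicate 1 (camera adjusted p = 0.0394). Starch metabolism (adjusted p = 0.0111) and cell wall enzymes (adjusted p = 0.0255) passed as higher by fry, which does not compare a list with other genes. Ribonucleotide reductase COCSUDRAFT_65254, which makes deoxynucleotides, rose from 167 ± 21.1 to 568 ± 220 CPM (SD, n = 3). Of 39 genes for mitosis and cyclins, 8 were higher and 4 lower, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.173). Cyclin-dependent kinase 1, COCSUDRAFT_65192, rose from 42.2 to 86.3 CPM and the cyclin COCSUDRAFT_22601 from 49.8 to 108 CPM. Among 86 transcription factors, 19 were higher and 11 lower, or 20 and 13 adjusted over the list alone, with a median of -0.02 and a mean of 0.16 that differ in sign (camera adjusted p = 0.815). The bZIP gene COCSUDRAFT_64454 rose from 7.37 to 28.2 CPM. Its camera direction was up, that of the mean. Medians and means were -0.07 and 0.04 for nitrogen, sulfur and amino acid metabolism, -0.06 and 0.04 for kinases and phosphatases, and -0.05 and 0.06 for proteases, each with a camera direction of down, that of the median. The list of transposable elements had 2 tested members, under the minimum of 5, and was not tested.

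Genes called higher lay next to each other more often than in random orders. The annotation of assembly GCF_000258705.1 matched all 9490 listed genes and was used for names, gene length and neighbours only, since the authors' build is not given in the sources used here. In gene order, 404 neighbouring pairs were both called higher, against a mean of 208 and a highest value of 252 in 10000 random orders (permutation p = 1e-04, the smallest they can give). A segmentation along the scaffolds gave 6 runs with a shifted median. Its thresholds were set after scaffold medians had been seen. The longest run held 348 tested genes from COCSUDRAFT_52946 to COCSUDRAFT_46926. Of these, 341 had a fold change above 0, 259 were called higher and 1 lower, and the median log2 fold change was 1.01. The medians in the 3 OX-labelled libraries were 0.94, 1.01 and 1.02. The other 183 tested genes of that scaffold had a median of -0.17. A further run, part of a scaffold, had a median of -0.44 (95 genes). The other runs were whole scaffolds without a change point, with medians of -0.36 (236 genes), 0.42 (158), 0.66 (55) and 0.58 (24). Those were picked by the cut on the median alone, with no permutation test of the shift. The genes called higher and lower in the further runs, in the order given, numbered 5 and 31, 23 and 73, 54 and 2, 27 and 1, and 13 and 0. The runs held 916 genes (10.7%), with 381 of the higher calls (28.5%) and 108 of the lower calls. The MADS-box gene lies in none of them. Without the genes of the runs, and adjusted over the rest, 1466 genes were called, 887 of them higher, and the same 7 lists were called.

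**Figure D3:**
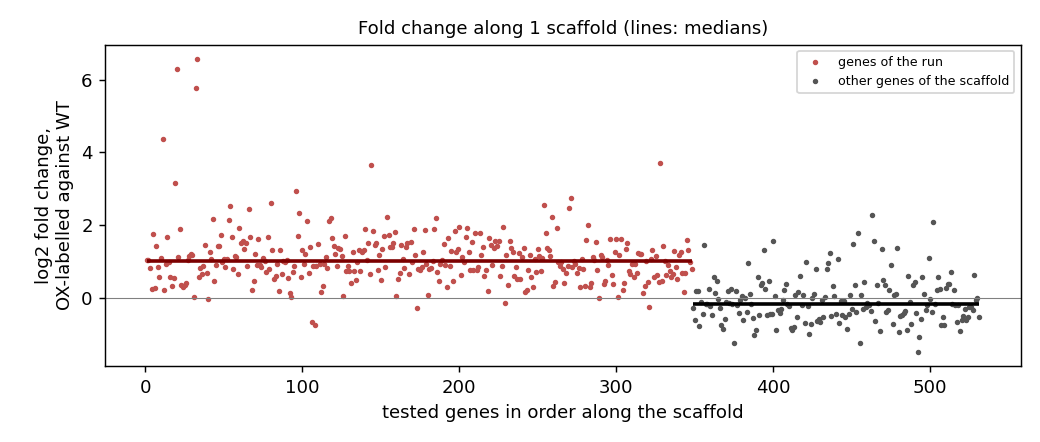
Log2 fold change of OX-labelled against WT libraries (y axis) for each tested gene of 1 scaffold in gene order (x axis, gene number), with the 348 genes of the run and the other 183 genes in separate colours and lines at their medians. The run has a median of 1.01, and the other genes of the scaffold have a median of -0.17.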

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

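Leaving out the shifted runs, the stray list members and OX replicate 3 for member counts were chosen after the data were seen, as were the runs and the ratios without each library. The total of 2107 genes ranged from 1050 to 2859 without 1 library, the higher genes (1337) from 737 to 1627 and the lower genes (770) from 313 to 1232; the cause was not tested, and leaving out OX replicate 3 raised the counts. The genes changed at least 2-fold (932) ranged from 709 to 1123 without 1 library, with 562 to 843 higher and 147 to 280 lower. At an adjusted p under 0.01, 966 genes were called, 760 higher and 206 lower. By glmTreat against a 2-fold change, 182 were called, 174 higher and 8 lower, since it tests a stricter hypothesis. Without the shifted runs 887 genes were higher. Scaling, filter and tool changed the total by less than 1.5 times, and 1907 to 2078 of the 2107 calls were shared with the fits that used other scalings, filters or tools, with no change of sign. For the MADS-box gene the log2 fold change passed the threshold with DESeq2 size factors (-0.52), library size only (-0.58), upper quartile factors (-0.54), no filter (-0.55), a CPM of at least 1 in 3 libraries (-0.55) and the DESeq2 Wald test (-0.53); the cause was not tested. Without 1 library it ranged from -0.61 to -0.45, not past the threshold. Of the 7 lists called, 0 passed camera with an estimated correlation (0 higher and 0 lower), while fry called 7, with 6 higher and 1 lower, of which 5 were among those called by camera; the cause was not tested. Without 1 library 6 to 8 lists were called. Without the stray members 7 were called, 4 higher and 3 lower. The direction of 6 lists that were not called turned: DNA repair without the shifted runs (adjusted p = 0.708), nitrogen and sulfur metabolism (0.40), kinases (0.788) and proteases (0.716) by fry, membrane transporters without WT replicate 2 (0.882) and OX replicate 3 (0.877), and transcription factors without WT replicate 2 (0.991). Without 1 library the adjusted p of these last lists ranged from 0.702 to 0.984 and from 0.702 to 0.993; the cause was not tested. Of the named genes' alternatives, 1043 kept side and direction and 7, all of COCSUDRAFT_10602, lost the call. The named genes were picked by fold change or p in these same data, so this does not speak for the other calls. The replicate block gave 2098 genes, 1957 of them shared with the 2107. Samples of the same number had deviations correlated at -0.16, 0.15 and 0.06. Of 6 libraries, 2 correlated best with their own number. These values gave no sign of a pairing by number but cannot exclude one. The median of the longest run ranged from 0.94 to 1.02 over the other fits. In data simulated at this depth and spread, with 100 genes changed 2-fold and 100 changed 4-fold, 55% and 98% of them were recovered. Far fewer genes changed there than were called here, so the share recovered in these data can differ.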

Other observations

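The tests of the MADS-box gene's label and of the longest run were chosen only after the result was seen, as was the group of cilium genes, and gene positions were looked at after the calls had been seen. Of 11 tested genes in that group, picked by flagellar, dynein or enkurin product names, 3 were higher in the OX-labelled libraries and 0 lower in edgeR. Among all 8575 tested genes, 1337 were higher and 770 lower. Besides the outer dynein arm heavy chain, the enkurin domain gene COCSUDRAFT_16080 had 2 counts over WT and 89 over the OX-labelled libraries, a ratio of 45.0 with an exact counting interval of 12.1 to 377. Both WT counts came from WT replicate 1, without which it was at least 19.1-fold higher, and the ratio was 29.3 (7.89 to 246) without WT replicate 2. The deflagellation-inducible gene COCSUDRAFT_53983 rose from 24.0 to 44.4 CPM. The other 8 did not pass.

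Several metabolic genes that rose lie in the longest run. These include the peroxiredoxin COCSUDRAFT_35935, which removes peroxides and rose from 20.4 to 126 CPM, and glucose-1-phosphate adenylyltransferase COCSUDRAFT_28274 of starch synthesis, which rose from 142 to 420 CPM. Outside the runs, the cellulase COCSUDRAFT_68186 rose from 35.7 to 114 CPM, and the type-II NADH dehydrogenase of mitochondria COCSUDRAFT_14988 fell from 70.3 to 32.9 CPM.

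The 1 gene with a MADS-box product name had a lower level in the libraries labelled as overexpressing CsubMADS1, but missed the threshold (edgeR adjusted p = 0.0535). A wrong label on 1 library is argued against, since 6 of 6 libraries correlated best with a library of their own group and the levels did not overlap. A swap of both labels stays open. The ratio of WT to OX-labelled libraries had an upper limit of 1.87, and without 1 library that limit ranged from 1.76 to 2.11, so a construct that raises this count about 2-fold is not excluded. A construct whose reads do not count at this locus, silencing, and a target other than this gene also stay open and were not tested.

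The long run of raised neighbours and the other runs are a second pattern. For genes called higher, chance order is argued against by the 404 neighbouring pairs, which include those of the long run. That count does not cover the runs with a median below 0. For the long run, a trend on gene length is argued against by its median of 0.91 after that trend was removed. A doubled copy number of the run may account for it, with a median of 1.01 overall. The medians were 1.02, 1.07 and 0.88 in its 3 classes of 116 genes by expression. For extra copies of whole scaffolds a median of at least 0.32 was asked, a bound that assumes a number of copies per cell. Of 27 scaffolds with 50 or more genes 3 reached it, 1 of them through the long run on part of it. Ploidy was not measured, so reaching the bound does not show a gain of copies. The runs with medians of -0.44 (95 genes) and -0.36 (236 genes, a whole scaffold) would need the opposite change of copies, which was not tested, and RNA levels alone do not separate a change of copies in either group from regional regulation. Outside the runs 160 neighbouring pairs were both higher, against at most 151 in 1000 random orders, and genotype stays open, as untested.

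The third pattern joins OX replicate 3, which stood apart on the second principal component (19.6% of variance, against 63.7% for the first, which separated the groups), and the list calls. Lower depth is argued against, since after thinning its distance to the other OX-labelled libraries was still 1.42 times that between those. RNA degradation was tested by the size, without the sign, of the correlation between a library's deviation and genomic gene length. In OX replicate 3 it was the largest (Spearman rho 0.43, genes not being independent replicates), with longer genes reading higher there. It was -0.30 and -0.27 in OX replicates 1 and 2, which partly mirror OX replicate 3 by construction. In WT replicates 1 to 3 it was 0.24, -0.28 and -0.02. The size met the prediction, but without a set sign it does not tell which library would be degraded, so degradation stays open. Of the 7 called lists, 6 kept call and direction without OX replicate 3, heat shock proteins being lost. After removal of the trend of the fold change on gene length, 7 kept both. The fold change had a Spearman rho of -0.01 with gene length, so there was little rising or falling trend to remove. Genotype and the growth state of the cultures stay open for the lists, as untested.

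The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2107 changed genes and the highest other 0, so that 1 split, the real one, gave as many. For genes changed at least 2-fold the values were 932 and 0, with 1 split again. Every other split mixes WT and OX-labelled libraries, so their difference becomes spread within groups and low gene counts follow. The contrast with 0 therefore decides nothing about chance. For gene lists the real split gave 7 and the highest other 10, and 4 splits gave as many, the real one included.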
